A study of Mus musculus with 25 samples.

How the data were processed

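The series profiled mouse trophoblast stem cells, the self-renewing precursors of the placenta, in 25 samples. In the Tet1 knockout experiment, 3 control and 3 Tet1 knockout samples each gave a library precipitated with an antibody against 5-methylcytosine (5mC, meDIP) and one precipitated with an antibody against 5-hydroxymethylcytosine (5hmC, hmeDIP). In the oxygen experiment, stem cells and cells differentiated for 3 days, each kept at 20% or 5% oxygen, gave 2 hmeDIP libraries and 1 RNA-seq library per condition. A single IgG precipitation served as background for both experiments. Samples labelled as replicates may be technical, since the sources used here do not say whether they are separate cultures. For the controls of the knockout experiment, repeats of the same DNA are argued against by their chromosome shares of reads. Shifts of these shares matched across the antibodies within a control number (correlations of 0.99 or more) but not between numbers (−0.381 at most). Genomic DNA was sonicated before precipitation, and RNA libraries came from a stranded mRNA kit, per the labels' protocols. Reads were trimmed with Trim Galore 0.6.0, and the tools named for alignment were HISAT2 2.1.0 and Bowtie2 2.3.2 against GRCm38, per the submitters' processing notes, which do not say which aligner served which assay.

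The deposited tables of the knockout and oxygen experiments give log2 values of reads over 2-kb windows, with each library scaled to nearly the same total within its experiment. The IgG table gives unscaled log2 reads, and the RNA table gives log2 reads-per-million (RPM) per gene, as the values themselves show. Windows and genes with no read are held in the tables at the value of 0.9 read. The other values of each library were whole multiples of the value of 1 read within 0.1% of the value (100% of them), so whole reads were recovered. The knockout and oxygen tables each hold 1048575 windows and end at 83764000 on chromosome 15, the line limit of a common spreadsheet program. The IgG table holds 1362779 windows. The remaining 314204 windows, on the rest of chromosome 15 and on the chromosomes listed after it, were not analysed here, so 76.9% of the windows entered the tests. No genome sequence was used. Gene positions were those of the RNA table, and 20872 of its 25965 genes had windows. Of 20677 gene names shared with a RefSeq list for GRCm38, 99.5% overlapped its position for the gene, and 66 names occurring more than once were left out. Exons and introns are not given in the sources used here, so windows were classed only as within 1000 bp of a transcription start, within a gene or outside genes.

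Tests, samples, gene lists, the rule for named genes and most alternatives were written before the data were examined. Windows were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend) on the log2 values, for windows whose mean was at or above the median of all windows. Windows were called at a Benjamini-Hochberg adjusted p under 0.05. The knockout comparison was fitted within each antibody (3 against 3), and the 8 hmeDIP libraries of the oxygen experiment were fitted together, so that their 4 groups of 2 shared one estimate of the spread. The written design provided a count test for tables of read counts; since the files hold log2 values, the limma test written for such values was used, and limma's voom on the recovered reads was added. No replicate block entered these fits. A test of gene bodies was added after the data were seen. It summed the recovered reads of all windows that overlap a gene at any point, so the value of a short gene also holds flanking sequence. The sums entered as log2 RPM with 0.5 reads added, for genes with a mean of at least 20 reads, and were tested with limma in the same way.

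Gene lists were tested with limma's camera on the mean log2 value of each gene's windows. Camera compared the change of a list's genes with the change of other genes, not their levels. A list called higher or lower therefore had a change above or below that of other genes. The preset inter-gene correlation was 0.01, and p was adjusted over the 15 lists of at least 5 genes in each comparison. The lists, of which 242 of 243 names were found, covered trophoblast stem cell, giant cell, spongiotrophoblast and syncytiotrophoblast genes. Others covered mitosis, the endocycle, targets of hypoxia-inducible factor (HIF), cytosine-modifying enzymes, FGF signalling, epithelial and mesenchymal genes, imprinted genes and germline genes. Markers of embryonic stem cells, fibroblasts and primitive endoderm, and mitochondrial transcripts (RNA only), were also listed. Named windows were the 12 largest rises and 12 largest falls among called windows in or at a gene whose groups did not overlap in any library, plus the windows of Tet1. Named RNA genes were the 12 largest rises and falls among protein-coding genes at or above the median level of genes with any signal. Any list member could be named as an example of its list. Gene bodies outside the lists were named after their values were seen.

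RNA had 1 library per condition, so no test was made across conditions. Log2 ratios, list medians and counts of genes past 2-fold used log2(RPM + 1), which understates changes of low genes. Folds printed for single genes are plain ratios of RPM, so they exceed those log2 ratios in low genes. Each plain ratio has a 95% interval from the reads of both libraries. A gene without a read was compared with a floor of 3 reads in that library. Intervals and floors cover counting error only. A list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Changes of 5hmC and RNA were compared by Spearman's rho across genes. Single values per library were compared by exact two-sided permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and version 1.17.8 of data.table were used, and plots were drawn with matplotlib 3.10.9.

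The test procedures were tested on simulated data drawn from the real libraries. For windows, 200 were changed 2-fold, 200 4-fold and 200 8-fold in the same simulation. For gene bodies, 200 each were changed 1.5-fold, 2-fold and 3-fold together, and for RNA 200 genes were changed. Every simulated window or gene of a comparison had the same extra spread, and no chromosome was shifted. Of windows changed 2-fold, limma recovered 23% in the 5hmC and 29.5% in the 5mC knockout comparison. In the oxygen experiment it recovered 14.5% (5% oxygen, stem cells), 14% (5% oxygen, differentiated cells), 17% (differentiation at 20% oxygen) and 9.5% (differentiation at 5%). At 4-fold the shares were 70.5%, 75.5%, 70.5%, 74.5%, 69.5% and 70% in the same order. Gene bodies changed 1.5-fold were recovered in 80.5%, 87%, 75.5%, 76%, 81.5% and 77% of cases in that order. Unchanged windows made up 0.631%, 1.38%, 8.01%, 0%, 0.915% and 3.86% of the window calls in that order, and unchanged genes 5.69%, 4.55%, 9.32%, 1.64%, 3.19% and 7.12% of the gene-body calls, so some shares exceeded the 5% aimed at. Camera called a list raised 1.25-fold in 20 of 20 simulations of the knockout 5hmC comparison. Genes in these lists were drawn independently and tested as summed reads. The simulations therefore do not show how camera behaves with correlated genes or with the mean log2 value of windows. For RNA, the 95% intervals held the simulated ratio for 97.5% of genes.

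Alternatives were quantile normalization, no trend, no filter on low windows or genes, only windows at least 1 log2 unit above IgG (IgG windows of at least 10 reads), a log2 change of at least 1 in addition to the test, and only the 4 libraries compared. Others were a replicate block, each library left out in turn, windows at transcription starts in place of gene bodies, an estimated correlation in camera, and an RNA pseudocount of 0.1. Voom, centring of each chromosome per library, thinning of the deepest library and summed reads in place of mean log2 values were added after the data were seen.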

Results

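Libraries of precipitated DNA came from 3 control and 3 Tet1 knockout samples of mouse trophoblast stem cells, each measured with antibodies against 5mC and 5hmC. A further 8 libraries measured 5hmC in stem cells and in cells differentiated for 3 days, at 20% and 5% oxygen, with 2 libraries per condition, and 4 RNA libraries covered the same conditions once each. The 6 meDIP libraries held 9723299 to 18343712 reads in the analysed windows, and the 6 hmeDIP libraries of the knockout experiment held 10682952 to 14585132. The oxygen experiment ranged from 10632304 reads (stem cells at 5% oxygen, replicate 2) to 47990665 (differentiated cells at 5% oxygen, replicate 1), and the others held at most 19701208. The IgG library held 56502162. A median window held 5 to 9 reads, or 23 in the deepest library and 50 in IgG. Replicates of a group correlated across windows at 0.722 to 0.89. RNA libraries held 25435845 reads in genes (stem cells, 20% oxygen), 27915682 (differentiated, 20%), 21031936 (stem, 5%) and 17839656 (differentiated, 5%), with no replicate of any condition. The RNA library of stem cells at 5% oxygen was entered in the series apart from the other 3. A batch difference of this library cannot be told apart from its condition. Relative to IgG, reads at transcription starts were 0.752 ± 0.028 (SD, n = 3) in control hmeDIP libraries and 0.779 ± 0.016 (n = 3) in knockout ones. In the oxygen experiment this ratio was 1.26 ± 0.02 (SD, n = 2) and 1.25 ± 0.11 (n = 2) in stem cells at 20% and 5% oxygen, and 1.33 ± 0.045 (n = 2) and 1.16 ± 0.091 (n = 2) in differentiated cells. Gene bodies lay at 1.08 in control and 0.985 in stem cells at 20% oxygen.

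The knockout comparison asked whether loss of Tet1, an enzyme that oxidises 5mC to 5hmC, alters the distribution of both marks. Tet1 itself (chromosome 10, 62804570 to 62899118, GRCm38) spans 50 windows, of which 36 were tested for 5hmC and 0 were called by limma, with log2 changes of −0.59 to 0.62 and a lowest adjusted p of 0.998. For 5mC, 42 of its windows were tested and 0 were called, with changes of −0.77 to 1.20 and a lowest adjusted p of 0.974. Every knockout library had reads in all 50 windows, which does not exclude a deletion that leaves part of each window, so the tables do not check the knockout label. Among genes of the spongiotrophoblast, a supporting layer of the placenta, the gene-body 5hmC change in the knockout was higher than among other genes (camera adjusted p = 0.0233, or 0.435 with an estimated correlation). In this list 9 of 12 genes had a higher mean. The median change was 0.11 against −0.04 for all genes by the mean log2 value of windows. By summed reads it was 0.112 against 0.00697, and the list was not called (camera adjusted p = 0.156). The imprinted growth suppressor Phlda2 changed by 0.58 (SE 0.22) and the pregnancy-specific glycoprotein gene Psg21 by 0.28 (SE 0.17), but 0 of the 12 members passed limma's test, also when adjusted over the list alone, and reads of the Psg family may be shared between near-identical copies. The list call ended without control replicate 1 (adjusted p = 0.0658), 2 (0.0856) or 3 (0.0522), without knockout replicate 2 (0.155) or 3 (0.05), and after centring of each chromosome (0.203). The other 14 lists had camera adjusted p of 0.155 to 0.993 for 5hmC and 15 lists had 0.388 to 0.893 for 5mC. Across all windows, limma called 0 of 524291 for 5hmC with 23631 (4.51%) at an unadjusted p under 0.05, and voom called 0. Gene bodies gave 0 calls among 17709 with limma (638 unadjusted) and 0 with voom. A simulated 1.5-fold change was recovered in 80.5% of gene bodies, but without chromosome shifts and with equal extra spread for all genes. Recovery in the real libraries may therefore be lower. In the 52450 windows richest in 5hmC in stem cells of the oxygen experiment, control libraries placed 18.7% ± 1.44 (SD, n = 3) of their reads and knockout libraries 20.2% ± 0.841 (n = 3), against 12.3% in IgG. This difference of 1.55 points had an exact permutation p of 0.2, where 3 against 3 libraries allow no p below 0.1, and it was 0.723 without control replicate 2. The hmeDIP libraries of the oxygen experiment, on some of which these windows were chosen, placed 36.0% to 40.2% of their reads there. The meDIP libraries placed 15.9% to 16.4%, closer to the hmeDIP libraries of the knockout experiment. Whether weaker enrichment of 5hmC in the knockout experiment hid changes was not tested.

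For 5mC, limma called 1 of 524288 windows, lower in the knockout, with 26056 at an unadjusted p under 0.05. This window lies in Egr3 (chromosome 14, 70080001 to 70082000), which encodes a zinc-finger transcription factor of the early growth response family. Its 5mC fell by 1.43 on the log2 scale (SE 0.215, limma adjusted p = 0.0308, n = 3 per group), from 39 to 92 reads in the controls to 18 to 43 in the knockout libraries. The call was lost without control replicate 1 (0 calls), control replicate 2 (0) or knockout replicate 3 (0). Counts rose to 58 without control replicate 3, 17 without knockout replicate 1 and 5 without knockout replicate 2. Voom called 31 windows, 30 of them lower. Gene bodies gave 0 of 17570 calls for 5mC with limma (798 unadjusted) and 0 with voom, and 1 call without control replicate 3. No window had lost 5hmC by the test, so 5mC was followed over the 10384 windows with lower 5hmC at an unadjusted p under 0.05, a set chosen after the data were seen. Relative to other windows of like 5hmC level, their mean 5mC log2 value was 0.28 ± 0.0349 (SD, n = 3) in controls and 0.24 ± 0.0156 (n = 3) in the knockout, a change of −0.03 (exact permutation p = 0.2). Its size ranged from −0.05 to −0.02 when single libraries were left out. Both antibodies read the same samples, so windows picked for fewer 5hmC reads may also hold less DNA. This would lower their 5mC reads too, and was not tested. Libraries of this experiment also differed in their reads per chromosome: the hmeDIP library of control replicate 2 lay at −0.29 (log2) on chromosome 1 and 0.31 on chromosome 8, whereas no library of the oxygen experiment was shifted by more than 0.03 in size.

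**Figure D1:**
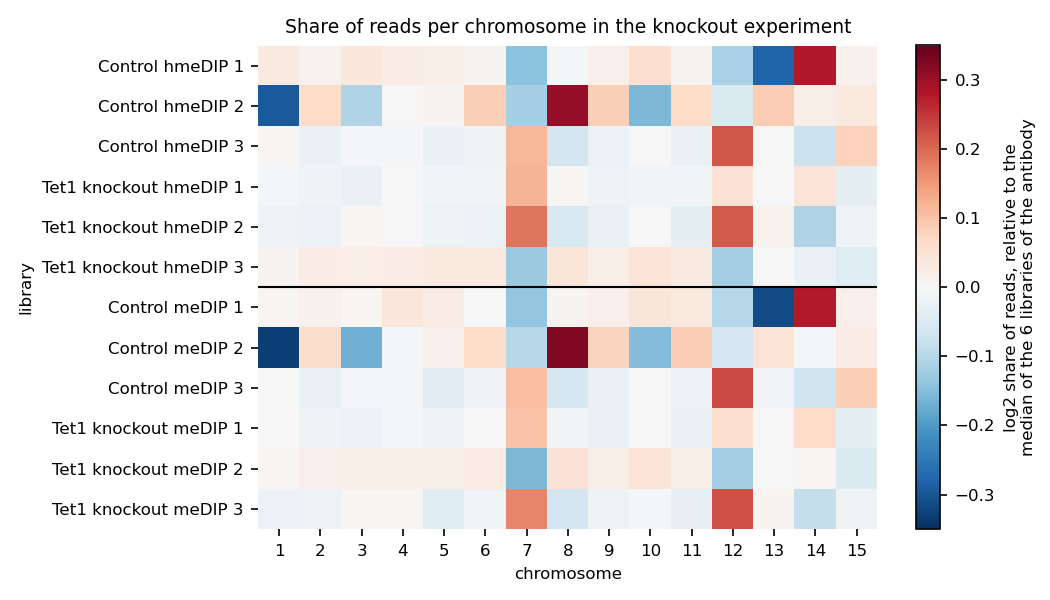
Share of reads per chromosome in each of the 12 libraries of the knockout experiment, as log2 relative to the median of the 6 libraries of the same antibody. Control replicate 2 lay at −0.29 on chromosome 1 and 0.31 on chromosome 8 in the hmeDIP library.

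Growth at 5% oxygen was compared with 20% to ask how low oxygen affects transcription and 5hmC. In stem cells, RNA of HIF targets was higher at 5% oxygen, with a list median of 0.71 (percentile 100 of matched random lists; 4 of 26 members at least 2-fold higher and 0 lower). Pfkfb3, a glycolytic regulator, was 3.98-fold higher (27.9 to 111 RPM, ratio interval 3.67 to 4.31). The stress-responsive gene Ndrg1 was 3.4-fold higher (85.5 to 291, interval 3.25 to 3.57). Trophoblast stem cell genes were lower, with a median of −0.47 (percentile 0). In this list 3 of 20 members were at least 2-fold lower and 0 higher. The 3 were Id2, an inhibitor of basic helix-loop-helix factors (154 to 62.4 RPM), Sox21 (47.9 to 22.3) and the FGF receptor gene Fgfr2 (99.2 to 48.7). Short of that mark on the log2 scale used, the trophectoderm factor Cdx2 went from 47.2 to 23.6 (ratio interval 0.451 to 0.553). Sox2, a core self-renewal factor of these cells, went from 403 to 247. Some members went the other way, among them Zic3 (40.6 to 69.2) and Klf5 (169 to 219). Epithelial and mesenchymal genes had a median of 0.54 (percentile 100), with the simple-epithelial keratins Krt18 (507 to 1180) and Krt19 (72.1 to 188) at least 2-fold higher. Cytosine-modifying enzymes had a median of −0.26 (percentile 0.84), with 0 of 13 members past 2-fold; Tet1 went from 122 to 85.5. The largest falls included the amino-acid stress gene Trib3 (17.5 to 3.0 RPM), the amino-acid transporter gene Slc1a4 (32.3 to 10.4) and the imprinted gene Peg3 (1340 to 454, interval 0.331 to 0.346). Among 8157 genes, 57 were at least 2-fold higher and 69 lower. Quantile scaling turned this into 70 and 58, so neither direction dominated. Medians of the remaining lists lay between −0.11 (imprinted genes, percentile 6.78) and 0.11 (mitosis, percentile 81.1), apart from mitochondrial transcripts. Giant cell, spongiotrophoblast, embryonic stem cell, fibroblast and primitive endoderm genes had medians of 0, FGF signalling −0.09, syncytiotrophoblast −0.07, endocycle −0.01 (0.04 after quantile scaling) and germline 0.06.

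**Figure D2:**
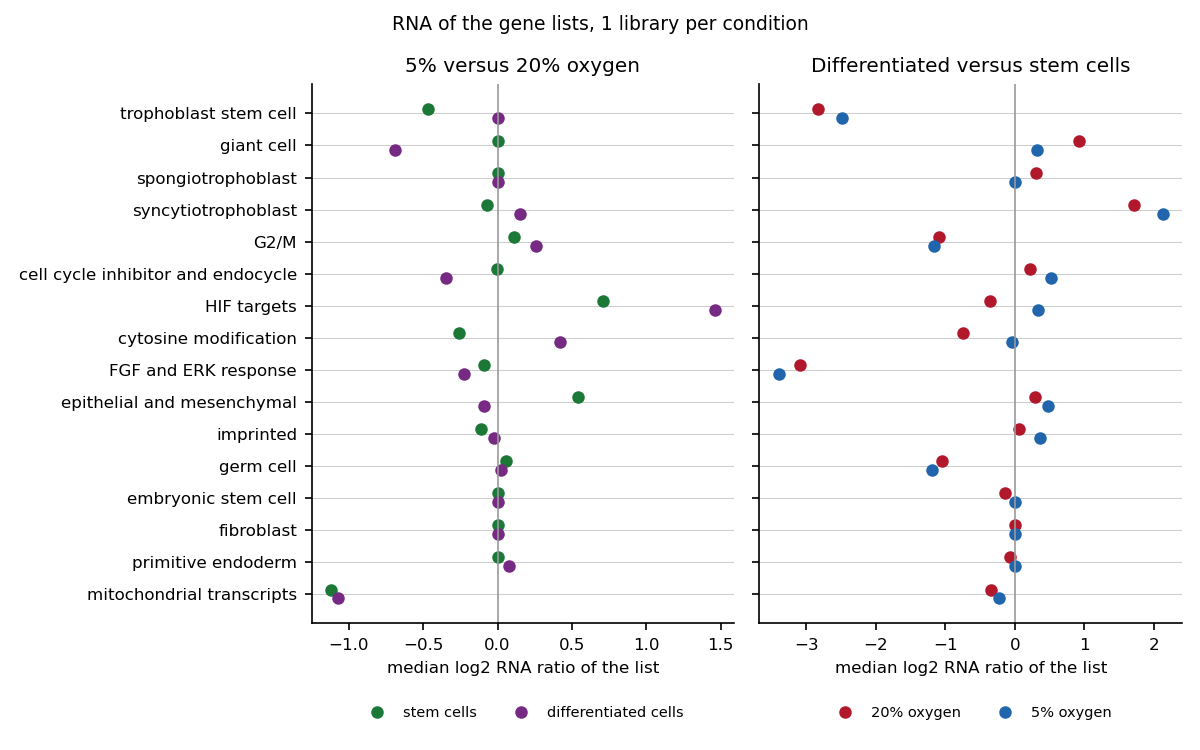
Median log2 RNA ratio of 16 gene lists fixed in advance, with 5% against 20% oxygen on the left (stem and differentiated cells) and differentiated against stem cells on the right (20% and 5% oxygen), from 1 library per condition. Points are list medians without error bars; HIF targets lay at 0.71 and 1.46 for oxygen, and trophoblast stem cell genes at −2.84 and −2.49 for differentiation.

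In the same stem cells, the gene-body 5hmC change at 5% oxygen was higher for HIF targets than for other genes (camera adjusted p = 0.000924, or 0.272 with an estimated correlation). The mean log2 value of windows was higher for 21 of 23 members, where its median change over genes with RNA reads was 0.07. By limma 6 members rose and 0 fell, and 11 rose when adjusted over the list alone; after quantile scaling these were 3 (Adm, Pfkfb3 and Tpi1) and 6. Adm, which encodes the vasodilator adrenomedullin (chromosome 7, 110627669 to 110629819), rose by 1.49 (SE 0.18, limma adjusted p = 1.33e-05), from 2.82 to 7.94 RPM. This gene spans only 2 windows, so its body value also holds its transcription start. Its RNA was low, at 1.14 RPM at 20% and 3.35 at 5% oxygen. The glycolytic enzyme gene Tpi1 rose by 0.70 (SE 0.16, adjusted p = 0.00938) and Pfkfb3 by 0.44 (SE 0.087, adjusted p = 0.0032). The glucose transporter gene Slc2a1 rose by 0.27 (SE 0.073) and the oxygen sensor gene Egln1 by 0.25 (SE 0.076). Syncytiotrophoblast genes were also higher as a list (camera adjusted p = 0.00544; adjusted p = 0.272 with an estimated correlation; 0.0617 without stem cells at 5% oxygen, replicate 2). Of its 11 members Dlx3, a homeobox gene of the labyrinth, rose by 0.55 (SE 0.12, limma adjusted p = 0.00856) and the other 10 did not pass; adjusted over the list alone 2 rose. FGF signalling genes missed the threshold as a list (camera adjusted p = 0.0603), while 3 of 9 rose (5 over the list alone), among them the feedback inhibitor Spry2 (0.93, SE 0.26), and 1 rose after quantile scaling (5 over the list alone). In the stem cell list 2 of 15 rose (4 over the list alone), Tead4 by 0.22 (SE 0.056) and Tfap2a by 0.36 (SE 0.093), and 0 after quantile scaling (3 over the list alone). The maintenance methyltransferase gene Dnmt1 rose by 0.26 (SE 0.071), and did not pass after quantile scaling (adjusted p = 0.121). Outside the lists, the tumour suppressor gene Hic1 rose by 1.09 (SE 0.13, limma adjusted p = 1.55e-05) and the T-cell co-receptor gene Cd8a fell by 1.02 (SE 0.21, adjusted p = 0.00503). In all, 849 of 18582 gene bodies rose and 61 fell. Quantile scaling, which moved the median of all genes from 0.05 to −0.01, gave 303 and 126. Limma without a trend called 2 gene bodies and the mean log2 value of windows gave 0 calls, so these counts and the members that rose depend on the fit. Without stem cells at 20% oxygen replicate 1 or 2, or stem cells at 5% replicate 2, the calls dropped to 104, 140 and 143, and without stem cells at 5% replicate 1 they rose to 1609.

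Single windows showed the same comparison at finer scale. Limma called 339 windows higher and 37 lower at 5% oxygen in stem cells. Of the higher windows 22.7% lay at transcription starts, against 5.43% of tested windows. Both windows of Adm and 2 of the 4 windows of Hic1, picked out after their values were seen, were called. A window in Spsb1, which encodes a substrate adaptor for ubiquitin ligases (chromosome 4, 149948001 to 149950000), rose by 2.16 (SE 0.324, adjusted p = 0.00327). One in the zinc-finger factor gene Klf6 (chromosome 13, 5870001 to 5872000) rose by 1.98 (SE 0.392, adjusted p = 0.0297). A window in Nt5dc3 (chromosome 10, 86810001 to 86812000), a nucleotidase-family gene, fell by 3.10 (SE 0.517, adjusted p = 0.00876). Named windows had few reads, 1 to 8 in the lowest library of each that rose. The counts rested on single libraries. There were 46 and 40 calls without stem cells at 20% oxygen replicate 1 and 2, while 5952 (1547 higher, 4405 lower) came without stem cells at 5% replicate 1 and 498 (91 higher, 407 lower) without its replicate 2. Voom called 921 windows (749 higher, 172 lower) and limma without a trend 0.

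**Figure D3:**
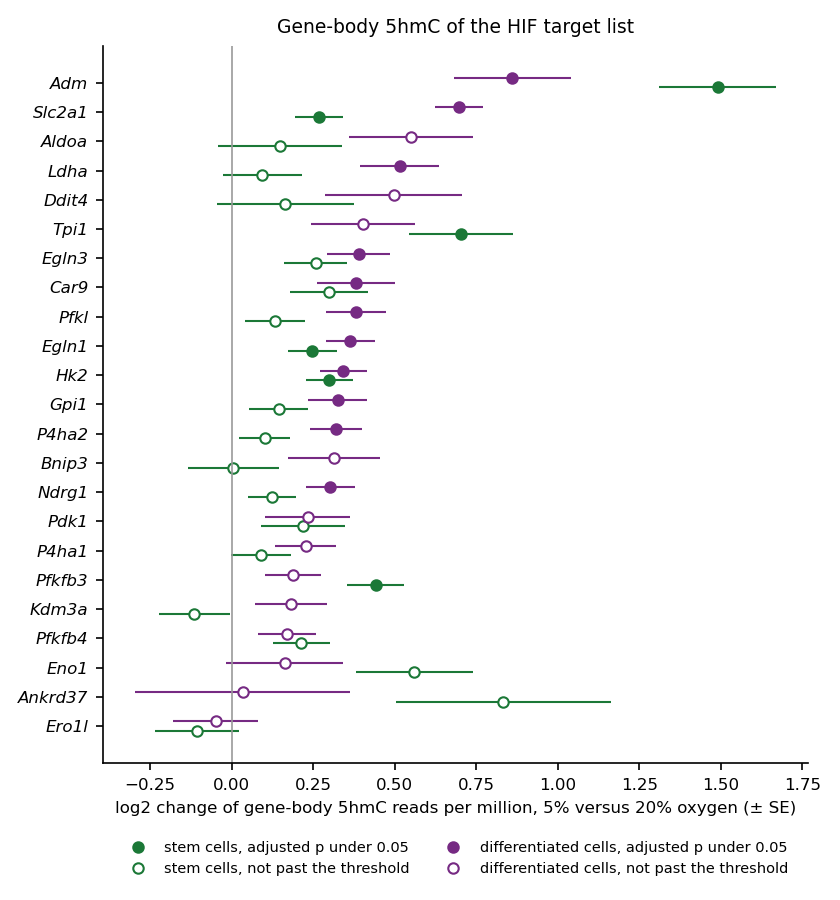
Change of gene-body 5hmC at 5% against 20% oxygen (log2, with standard error from limma, 2 libraries per group) for the 23 HIF targets with windows, in stem and in differentiated cells. Filled points passed an adjusted p of 0.05 over all genes; 6 did in stem cells and 11 in differentiated cells before quantile scaling, and 3 and 2 after it.

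In differentiated cells the RNA difference between 5% and 20% oxygen was wider. HIF targets had a median of 1.46 (1.41 after quantile scaling; percentile 100), with 18 of 26 members at least 2-fold higher and 0 lower. Egln1 was 8.77-fold higher (20.7 to 181 RPM, interval 8.06 to 9.57) and the mitophagy gene Bnip3 went from 71.1 to 345. Beyond the list, the neuronal-type glucose transporter gene Slc2a3 was 29.2-fold higher (50.5 to 1470, interval 27.7 to 30.7) and the carbonic anhydrase gene Car12 20.7-fold higher (3.61 to 74.6, interval 17.0 to 25.4). Trophoblast giant cell genes were lower, with a median of −0.69 (percentile 0; −0.97 with genes without a read at their bound), 6 of 16 members at least 2-fold lower and 1 higher. Ctsj, a placental cathepsin, went from 144 to 47.6 and Hand1, which drives giant cell formation, from 335 to 166. A mean of at least 1 RPM over both libraries was reached by 10 of the 16 members. Endocycle genes had a median of −0.34 (percentile 0.78), and the cyclin-dependent kinase inhibitor gene Cdkn1c went from 1760 to 407. The syncytiotrophoblast list split, with a median of 0.15 (percentile 68.4), 3 of 14 higher and 2 lower. Syna, an envelope-derived fusion gene, was 8.06-fold lower (133 to 16.5, interval 0.11 to 0.139), whereas Gcm1, the transcription factor gene of the same lineage, went from 2.29 to 16.2. Cytosine-modifying enzymes had a median of 0.42 (percentile 95.6). Tet1 was 3.9-fold higher (10.0 to 39.0, interval 3.41 to 4.47), and Tet2 (11.1 to 37.0) and Dnmt3l (59.0 to 162) also passed 2-fold. The thyroid-hormone deiodinase gene Dio3 went from 102 to 10.1. Members of the Serpinb9 family, whose reads may be shared between similar copies, were also lower, Serpinb9e from 196 to 28.1. Among 7942 genes 607 were at least 2-fold higher and 301 lower, or 495 and 395 after quantile scaling. Medians were 0.26 for mitosis, −0.22 for FGF signalling, −0.09 for epithelial and mesenchymal genes (0.03 after quantile scaling, 0.05 at the bound) and −0.02 for imprinted genes. They were 0.03 for germline and 0.08 for primitive endoderm genes, and 0 for stem cell, spongiotrophoblast, embryonic stem cell and fibroblast genes.

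For 5hmC in differentiated cells, the median of all gene bodies was 0.10 at 5% against 20% oxygen and −0.01 after quantile scaling, so changes are given after that scaling. The change was again higher for HIF targets than for other genes (camera adjusted p = 2.48e-07, or 0.18 with an estimated correlation), with a median gene-body change of 0.23. Without scaling, the mean log2 value of windows was higher for 23 of 23 members, where its median change over genes with RNA reads was 0.16. Before scaling 11 of the 23 rose by limma and 0 fell, and 15 rose when adjusted over the list alone. After scaling 2 rose (Slc2a1 and Adm) and 0 fell, and 10 rose over the list alone. Slc2a1 rose by 0.60 (0.70 before scaling, SE 0.073, limma adjusted p = 3.8e-07). Adm rose by 0.72 (0.86 before scaling, SE 0.18, adjusted p = 0.0017) and the lactate dehydrogenase gene Ldha by 0.39 (0.52 before scaling, SE 0.12, adjusted p = 0.00405, or 0.0647 after scaling). RNA of Adm, by contrast, went from 3.67 RPM at 20% to 2.58 at 5% oxygen. Epithelial and mesenchymal genes were higher as a list (camera adjusted p = 0.0389; adjusted p = 0.329 with an estimated correlation). Of 9 members 3 rose before scaling, and 4 when adjusted over the list alone. After scaling 1 rose, the E-cadherin gene Cdh1 (0.30), and 2 over the list alone. That call ended without differentiated cells at 20% oxygen replicate 1 (adjusted p = 0.17) or at 5% replicate 2 (0.119), and without stem cells at 5% replicate 1 (0.0684) or 2 (0.0508). It also ended with summed reads (0.0615) and at transcription starts (0.234). In the stem cell list, not called (camera adjusted p = 0.41), 5 of 15 members rose before scaling (6 over the list alone). After scaling 2 rose (4 over the list alone), the trophoblast factor gene Tfap2c (0.49) and the FGF receptor gene Fgfr2 (0.31). Dnmt1 rose by 0.29 (adjusted p = 0.0247 after scaling). Outside the lists, the selenium enzyme gene Sephs2 rose by 1.84 (2.00 before scaling, SE 0.31, adjusted p = 7.9e-05) and Hic1 by 1.00 (1.12 before, SE 0.13, adjusted p = 3.97e-06). Rptn, an epidermal gene, fell by 1.22. Gene-body calls numbered 1673 higher and 22 lower, or 330 and 65 after quantile scaling. Limma without a trend called 0 (3575 at an unadjusted p under 0.05) and the mean log2 value of windows gave 0 (3299 unadjusted), so the member counts above depend on the fit as well. The calls dropped to 517 without differentiated cells at 20% replicate 2, 647 without those at 5% replicate 1 and 279 without those at 5% replicate 2. Of gene bodies higher at 5% oxygen in both cell states there were 443 before scaling, where 76.4 would be shared by independent lists, and 91 after it, where 5.38 would be. These expected numbers leave out that both comparisons used the same estimate of spread for each gene.

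At the level of windows, limma called 346 higher and 0 lower in differentiated cells at 5% oxygen, with 32929 of all windows at an unadjusted p under 0.05; voom called 983 higher and 65 lower, and limma without a trend 0. Transcription starts held 26.9% of the called windows, although reads at starts as a class, relative to IgG, were 1.16 at 5% against 1.33 at 20% oxygen. A window in Mpzl1, an adhesion receptor gene (chromosome 1, 165624001 to 165626000), rose by 2.52 (SE 0.435, adjusted p = 0.00967), and one in the thyrotropin receptor gene Tshr by 2.31 (SE 0.421, adjusted p = 0.0141). Of 185 windows in Maml3, a Notch coactivator gene picked out after its values were seen, 3 were called. The call count was 0 without differentiated cells at 5% replicate 2, 151 (56 higher, 95 lower) without its replicate 1, and 208 without those at 20% replicate 1. In both cell states 39 windows were called higher, where 0.224 would be shared by independent lists. This expected number leaves out that both comparisons used the same estimate of spread for each window. The oxygen effect in differentiated cells was compared with that in stem cells by an interaction term. Limma called 0 windows (26167 unadjusted; voom 15) and 0 of 18582 gene bodies (1158 unadjusted; voom 13), and camera adjusted p over the lists was 0.327 to 0.954, so the oxygen effects of the 2 states were not shown to differ. Leaving out stem cells at 5% replicate 1 gave 277 windows, and leaving out its replicate 2 gave 7 windows and 17 gene bodies; 1 window came without differentiated cells at 5% replicate 1.

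Differentiation was compared with the stem cell state at each oxygen level to ask how 5hmC and RNA move as cells leave self-renewal. At 20% oxygen the RNA of trophoblast stem cell genes was lower, with a median of −2.84 (percentile 0), 15 of 20 members at least 2-fold lower and 1 higher. Sox2 was 1540-fold lower (403 to 0.262 RPM, ratio interval 0.000281 to 0.00128), the T-box factor Eomes 359-fold lower (177 to 0.492) and the orphan receptor Esrrb 198-fold lower (273 to 1.38). FGF signalling genes had a median of −3.10 (percentile 0; 10 of 14 lower, 0 higher), with the feedback inhibitor Spry4 going from 57.9 to 0.164. Genes of the syncytiotrophoblast, the fused exchange layer, were higher, with a median of 1.71 (percentile 100; 9 of 14 higher, 0 lower). Syna was 933-fold higher (0.143 to 133, interval 364 to 3430) and Dlx3 went from 8.02 to 275. Giant cell genes had a median of 0.92 (2.04 with genes without a read at their bound; percentile 100; 7 of 16 higher, 0 lower) and spongiotrophoblast genes 0.30 (0.38 at the bound; percentile 99.6; 6 of 15 higher, 1 lower), with Phlda2 going from 5.67 to 166. A mean of at least 1 RPM over both libraries was reached by 10 of 16 giant cell and 8 of 15 spongiotrophoblast genes. Some members stayed low in differentiated cells, among them Prl3d1 (0.328 RPM), Prl2c2 (0.0328), Prl3b1 (0), Tpbpa (1.7) and Tpbpb (0). Mitosis genes had a median of −1.09 (percentile 0; 13 of 19 lower, 0 higher), with the proliferation marker Mki67 going from 1860 to 547, and Cdkn1c was 24.7-fold higher (71.2 to 1760). The adipogenic and placental receptor gene Pparg was 672-fold higher (0.249 to 168, interval 326 to 1670) and the placental kinase gene Nrk 101-fold higher (11.1 to 1120, interval 90.4 to 113). Against the floor of 3 reads, the zinc-finger factor Zic5 (143 to 0) was at least 1460-fold lower (upper limit of the ratio interval 0.000844) and Dio3 (0 to 102) at least 955-fold higher (lower limit 776). Cytosine-modifying enzymes had a median of −0.75 (percentile 0.37; 4 of 13 lower, 0 higher); Tet1 was 12.2-fold lower (122 to 10.0, interval 0.0729 to 0.0925). HIF targets had a median of −0.35 (percentile 2.66), with 5 higher and 8 lower. Endocycle genes had a median of 0.22, epithelial and mesenchymal genes 0.29 and imprinted genes 0.07. Germline genes lay at −1.05 (−1.75 at the bound; percentile 0), embryonic stem cell genes at −0.15, fibroblast genes at 0 and primitive endoderm genes at −0.07. Among 8310 genes 1149 were at least 2-fold higher and 1091 lower, or 1073 and 1151 after quantile scaling.

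At 5% oxygen the same lists led. Stem cell genes had a median of −2.49 (percentile 0; 12 of 20 lower, 2 higher) and FGF signalling genes −3.40 (percentile 0; 11 of 14 lower, 0 higher). Sox2 went from 247 to 0.0516 RPM (ratio interval 5.28e-06 to 0.00116, from 1 read in differentiated cells) and Eomes from 133 to 0.155 (interval 0.000241 to 0.00341, from 3 reads). Syncytiotrophoblast genes had a median of 2.13 (percentile 100; 10 of 14 higher, 0 lower), and Gcm1 (0 to 16.2) was at least 124-fold higher against the floor (lower limit of the interval 101). The trophoblast factor gene Gata2 was 82.2-fold higher (5.78 to 476, interval 69.3 to 98.4) and Nrk 118-fold higher (11.7 to 1380, interval 105 to 134). Giant cell genes had a median of 0.32 (percentile 99.3; 3 of 16 higher, 0 lower), mitosis genes −1.17 (percentile 0; 12 of 19 lower, 0 higher) and imprinted genes 0.36 (percentile 97.1; 8 of 17 higher, 3 lower). Of the giant cell genes, 5 of 16 reached a mean of 1 RPM over both libraries. Tet1 was 2.19-fold lower (85.5 to 39.0, interval 0.419 to 0.496). Medians were 0.48 for epithelial and mesenchymal, 0.53 for endocycle, 0.33 for HIF target, −0.04 for cytosine-modifying and −1.19 for germline genes (−1.26 at the bound), and 0 for spongiotrophoblast, embryonic stem cell, fibroblast and primitive endoderm genes. Among 8110 genes 1364 were at least 2-fold higher and 780 lower, a split that quantile scaling turned into 1045 and 989.

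For 5hmC on differentiation at 20% oxygen, the change of stem cell genes was lower than that of other genes (camera adjusted p = 0.0134, or 0.309 with an estimated correlation). By limma 2 of 15 members fell and 0 rose, also when adjusted over the list alone: Esrrb (−0.22, SE 0.056, limma adjusted p = 0.0319) and the Krüppel-like factor gene Klf5 (−0.60, SE 0.17, adjusted p = 0.0458, or 0.073 after quantile scaling). FGF signalling genes were lower (camera adjusted p = 0.006; adjusted p = 0.308 with an estimated correlation), and 1 of 9 fell, Spry2 (−1.08, SE 0.26, adjusted p = 0.0187), or 4 over the list alone. Syncytiotrophoblast genes were called as a list (camera adjusted p = 0.0204, or 0.308 with an estimated correlation) although 0 of 11 members passed in either adjustment before quantile scaling. After it 2 rose over the list alone. By summed reads before scaling the list median was 0.08 against −0.03 for all genes. The stem cell call ended without differentiated cells at 20% replicate 2 (0.0739) or stem cells at 20% replicate 2 (0.0872). The FGF call ended without differentiated cells replicate 1 (0.0811) or stem cells replicate 2 (0.0872), and the syncytiotrophoblast call without differentiated cells replicate 2 (0.316), stem cells replicate 1 (0.13) or 2 (0.0622), with summed reads (0.0712) and at transcription starts (0.87). The body of Tet1 fell (−0.28, SE 0.07, adjusted p = 0.0277). Outside the lists, the acyl-CoA-binding gene Dbi rose by 1.29 (SE 0.17, adjusted p = 3e-05) and the epithelial factor gene Elf3 by 1.15 (SE 0.13, adjusted p = 2.27e-06), while the growth factor gene Gdf7 fell (−1.06, SE 0.16, adjusted p = 0.000121). Gene-body calls were 197 higher and 244 lower, or 244 and 168 after quantile scaling, with 8 calls without a trend and 3 by the mean log2 value of windows. They numbered 146 and 142 without differentiated cells replicate 1 and 2, and 108 and 60 without stem cells replicate 1 and 2. Limma called 1395 windows higher and 1019 lower, and 0 without a trend. A window in Eif2c2, which encodes Argonaute 2 (chromosome 15, 73126001 to 73128000), rose by 3.42 (SE 0.298, adjusted p = 7.16e-09) and one in the DNA-replication gene Rpa1 (chromosome 11, 75314001 to 75316000) by 3.60 (SE 0.475, adjusted p = 2.89e-05). A window in the neural factor gene Myt1l (chromosome 12, 29748001 to 29750000) fell (−3.25, SE 0.592, adjusted p = 0.00276). Of the lower windows 14.4% lay at transcription starts, against 4.52% of the higher ones. Without differentiated cells replicate 1 the counts were 371 higher and 652 lower; totals were 1111 without its replicate 2, and 832 and 675 without stem cells replicate 1 and 2.

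At 5% oxygen, the stem cell list was lower again (camera adjusted p = 0.0398; adjusted p = 0.568 with an estimated correlation), with 6 of 15 members that fell and 1 that rose by limma, or 7 and 2 when adjusted over the list alone. Those that fell included Cdx2 (−0.70, SE 0.18, adjusted p = 0.0126), Eomes (−0.59, SE 0.14, adjusted p = 0.00491) and Esrrb (−0.35, SE 0.056, adjusted p = 6.92e-05), and Tfap2c rose by 0.48 (SE 0.13). FGF signalling genes were lower (camera adjusted p = 0.0413; adjusted p = 0.568 with an estimated correlation), with 3 of 9 that fell, or 4 over the list alone: Spry2 (−1.49, SE 0.26), the ETS factor gene Etv4 (−0.57, SE 0.1) and the phosphatase gene Dusp6 (−0.91, SE 0.27). The stem cell call ended without stem cells at 5% replicate 2 (0.12), differentiated cells at 5% replicate 1 (0.0659) or those at 20% replicate 1 (0.0518) or 2 (0.0512). The FGF call ended without stem cells at 5% replicate 1 (0.103) or 2 (0.0767), differentiated cells at 5% replicate 1 (0.0659) or those at 20% replicate 1 (0.0678) or 2 (0.0672). HIF targets were not called as a list on differentiation, but 5 of 23 rose and 1 fell at 5% oxygen (7 and 2 over the list alone), and 1 rose and 1 fell at 20% (5 and 3 over the list alone). Their largest rise was P4ha2, a collagen prolyl hydroxylase gene (0.60, SE 0.079, adjusted p = 3.52e-06). Dnmt1 rose by 0.37 and Tet3, which oxidises 5mC, by 0.28. Giant cell, germline and embryonic stem cell lists had 0 members past the test in any of the 4 oxygen and differentiation comparisons before quantile scaling. After it 1 giant cell gene rose over the list alone on differentiation at 20% oxygen. Gene-body calls were 912 higher and 606 lower (219 calls without a trend and 11 by the mean log2 value of windows; 580 and 449 calls without differentiated cells at 5% replicate 1 and 2). Limma called 3601 windows higher and 2232 lower, and 0 without a trend. The calls were led by Rpa1 (4.72, SE 0.475, adjusted p = 1e-07). A well-covered window in Dock6, a Rho-family exchange factor gene (chromosome 9, 21830001 to 21832000), rose by 3.23 (SE 0.199, limma adjusted p = 3.16e-13) from 14 to 16 reads to 153 to 583. These reads are not scaled to depth, and differentiated cells at 5% oxygen held 47990665 reads in replicate 1 against 14078496 in replicate 2. Totals were 2395 and 668 without differentiated cells at 5% replicate 1 and 2, and 10424 without stem cells at 5% replicate 1. Both oxygen levels shared 857 higher and 358 lower windows, where 9.58 and 4.34 would be shared by independent lists, and 170 higher and 138 lower gene bodies, where 9.67 and 7.96 would be. The comparisons took each spread from the same fit, so lists may overlap beyond these expected numbers without a common effect.

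The change of gene-body 5hmC was ranked against the change of RNA across genes, which are not independent replicates, in 4 comparisons. On differentiation rho was 0.19 at 20% oxygen (13008 genes) and 0.241 at 5% (12703 genes), with ranges of 0.164 to 0.177 and 0.201 to 0.238 when single libraries were left out. For 5% against 20% oxygen rho was 0.0103 in stem cells (12762 genes) and 0.026 in differentiated cells (12407 genes). On differentiation at 20% oxygen, the 650 genes with the largest RNA rise had a median 5hmC change of 0.06 and the 650 with the largest fall −0.11, against −0.03 for all genes (percentiles 100 and 0 of matched random lists). At 5% oxygen the 635 genes at each end had medians of 0.19 and −0.09, against 0.05 for all genes (percentiles 100 and 0). In stem cells at 5% oxygen the 638 genes with the largest RNA rise had a median of 0.11 against 0.07 for all genes (percentile 100). The 620 such genes in differentiated cells had 0.20 against 0.16 (percentile 99.9), and the genes with the largest falls lay at percentiles 49.2 and 29.2. Window by window, the 5hmC change in the Tet1 knockout and that on differentiation at 20% oxygen had a Pearson's r of −0.00181 and a Spearman's rho of −0.00123 (462084 windows that are not independent replicates; rho of −0.0142 to 0.017 with single libraries left out). Since the knockout changes held 0 called windows, these values show neither a relation nor its absence.

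**Figure D4:**
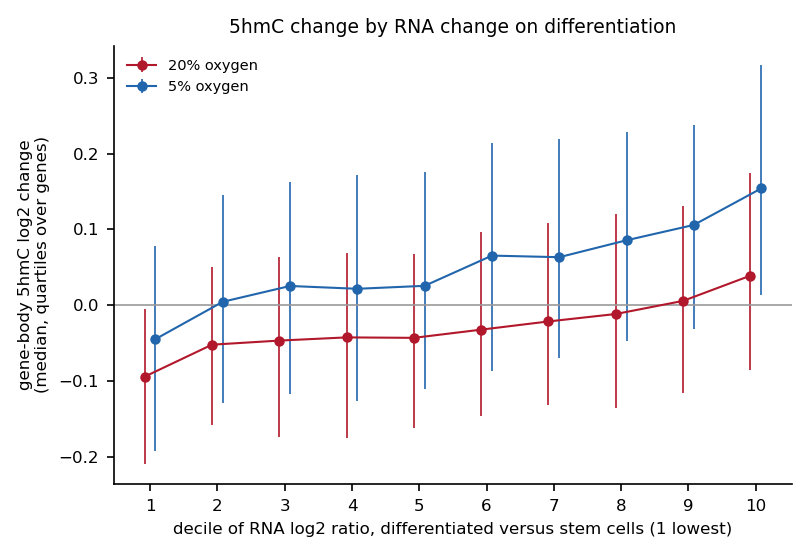
Change of gene-body 5hmC (log2) in deciles of genes ordered by their RNA change on differentiation at 20% and 5% oxygen. Points are medians and bars the quartiles across genes; the medians ran from −0.09 to 0.04 at 20% oxygen and from −0.04 to 0.15 at 5%.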

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

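RNA was not tested across conditions, since it had 1 library each, and the gene-body test of 5hmC was added after the data were seen. Among the members of the fixed lists, Id2 stood out because its RNA moved at least 2-fold in opposite directions with oxygen in the 2 cell states. Its log2 ratio of 5% to 20% oxygen was −1.29 in stem cells (154 to 62.4 RPM, ratio interval 0.382 to 0.43) and 1.96 in differentiated cells (19.8 to 79.9, interval 3.68 to 4.45). The difference between the cell states was not tested, and no explanation for it was tested. Gene-body 5hmC of Id2 differed at 5% oxygen in differentiated cells by 0.52 after quantile scaling (0.65 before, SE 0.21, limma adjusted p = 0.0417 before scaling and 0.183 after it, n = 2 per group).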

How the results depend on the processing

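Voom, the chromosome-centred fits, thinning and summed reads, and all results for gene bodies and for 5mC at windows lower in 5hmC, were added after the data were seen. There were 404 combinations of a result and an alternative. With a library left out, 129 kept their side of the threshold, stayed within 1.5 times a count or moved by less than their spread, 53 moved further and 26 fell short of the threshold. With another setting these were 132, 40 and 24. Gene lists called by camera kept their direction in these, but counts were compared by size alone. With quantile scaling the larger share changed from lower to higher calls for gene bodies on differentiation at 20% oxygen and for RNA with oxygen in stem cells, and from higher to lower for RNA on differentiation at 20%. The cause was not tested unless stated. In the following, the order is 5% oxygen in stem cells, 5% oxygen in differentiated cells, differentiation at 20% and differentiation at 5%. Without a trend limma called 0, 0, 0 and 0 windows and 2, 0, 8 and 219 gene bodies, and 0 windows for 5mC in the knockout. Voom called 921 and 1048 windows with oxygen, 11220 with differentiation at 5%, 15 windows and 13 gene bodies in the interaction, and 31 windows for 5mC. Only windows above IgG gave 655 and 1422 calls for differentiation, from fewer windows tested, and 14 for 5mC. The other 5mC values were 73 with no filter and 22 with chromosomes centred. With only the 4 libraries compared, 864 windows were called for oxygen in differentiated cells. Gene bodies by mean log2 value gave 0, 0, 3 and 11 calls, and quantile scaling gave 429 and 395 for oxygen. With no filter, from more genes considered, 238, 1442, 3679 and 3678 RNA ratios passed 2-fold. Lists called by camera went from 10 to 0 with an estimated correlation and 0 at transcription starts. The relation of 5hmC and RNA was 0.032 for oxygen in stem cells at transcription starts and 0.032 in genes at or above the median RNA signal, and 0.112 and 0.146 for differentiation at transcription starts.

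With single libraries left out, the lone library was taken to vary like the other groups. Windows ranged from 40 to 5952, 0 to 271, 675 to 1111 and 668 to 10424 in that order, 0 to 277 in the interaction, 0 to 0 for 5hmC and 0 to 58 for 5mC in the knockout. Gene bodies ranged from 104 to 1609, 279 to 1538, 60 to 146 and 449 to 1458, 0 to 17 in the interaction, 0 to 0 for 5hmC and 0 to 1 for 5mC. List calls ranged from 6 to 12. The 5mC change at windows lower in 5hmC ranged from −0.05 to −0.02 (−0.0519 to −0.0175) and the share in rich windows differed by 0.7229 to 2 points. Rho of 5hmC and RNA ranged from 0.00121 to 0.0141, 0.00849 to 0.0415, 0.164 to 0.177 and 0.201 to 0.238, and that of knockout and differentiation from −0.0142 to 0.017.

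Same-numbered samples did not deviate together (correlations of −0.0832 to 0.049 in the knockout experiment and 0.00324 to 0.0344 in the oxygen experiment), so the replicate numbers were not taken to pair samples. A replicate block gave 604, 521, 2949 and 6782 windows, 0 in the interaction, 0 for 5hmC and 67 for 5mC in the knockout. It gave 1151, 1905, 521 and 1674 gene bodies and 12 list calls, and the 5mC change at windows lower in 5hmC had an exact p of 0.25. No paired analysis was possible because RNA had 1 library per condition, and none was made for relations across genes or windows. The planned 5mC change at windows that lost 5hmC gave no value, since 0 windows were lost. Alternatives for read counts, and a window pseudocount, did not apply to log2 values. Changes of 2-fold were recovered in 9.5% to 29.5% of simulated windows.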

Other observations

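Tests of copy number, of an exchange of knockout numbers, and of other splits for the window results were chosen after the results were seen. Mitochondrial transcripts were lower at 5% oxygen, with a median RNA log2 ratio of −1.12 in stem cells (percentile 0; 8 of 9 at least 2-fold lower) and −1.07 in differentiated cells (percentile 0; 5 of 9 lower; −0.77 after quantile scaling). The cytochrome b transcript mt-Cytb held 7100 and 1690 RPM in stem cells at 20% and 5% oxygen, and 8480 and 1650 in differentiated cells. On differentiation their median was −0.34 at 20% oxygen (−0.08 after quantile scaling) and −0.23 at 5% (0 after it). This list was fixed in advance as a measure of RNA quality. Mitochondrial reads made up 9.02% and 4.23% of reads in genes in stem cells at 20% and 5% oxygen. In differentiated cells they made up 6.91% and 3.85%. With 1 library per condition, oxygen cannot be told apart from RNA quality or preparation here. Among enzymes acting on cytosine, Dnmt3b went from 404 to 81.7 on differentiation at 20% oxygen and from 301 to 110 at 5%. Dnmt1 went from 467 to 600 and from 422 to 618, and Tet3 from 10.3 to 17.1 and from 8.0 to 34.3. Of germline genes, the meiotic gene Sycp3 went from 22.2 to 0.688 and from 50.4 to 0.98. Imprinted genes went both ways on differentiation, with 6 of 17 at least 2-fold higher and 4 lower at 20% oxygen. Peg10 went from 975 to 4880 and from 657 to 4430, and H19 from 16.1 to 64.9 and from 17.7 to 124, whereas Mest went from 27.6 to 6.06 and from 15.7 to 2.89. Marker genes of other cells were mixed. In stem cells at 20% oxygen Col1a1 (fibroblasts) lay at 0.713 and the pluripotency factor Pou5f1 at 0.998, while Sparc (568), Dppa4 (131), Zfp42 (110), Dab2 (18.9) and Utf1 (12.2) of those lists were expressed. The fibroblast marker Pdgfra lay at 2.85 there and at 27.5 in differentiated cells at 20% oxygen. Across genes, 5hmC of gene bodies relative to IgG in stem cells at 20% oxygen was 1.19 in the lowest and 0.889 in the highest class of 3 by RNA level, and 0.996 in genes without a read.

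The change of gene-body 5hmC at 5% oxygen was higher for HIF targets than for other genes in both cell states. A shift shared by genes of like length, RNA level and 5hmC level is argued against by list medians at percentile 99.79 (stem cells) and 99.98 (differentiated cells) of 10000 matched random lists. Matching used coarse classes of these properties. Over all genes, 5hmC relative to IgG also moved with oxygen by RNA level. In differentiated cells it went from 0.893 at 20% to 0.998 at 5% oxygen in the highest RNA class. In genes without a read it went from 1.11 to 0.965. Differences in RNA level within the classes, and base composition, which was not matched, stay open. With all 8 libraries thinned to the depth of the shallowest, the percentiles were 99.97 and 99.98, which argues against unequal depth. Without windows within 1000 bp of a transcription start, the percentile was 99.98 in differentiated cells, against a shift confined to starts, and 96.42 in stem cells, which leaves that explanation open there. Whether hypoxic transcription and 5hmC over these genes are linked was not tested, and across all genes the changes of 5hmC and RNA with oxygen had a rho of 0.0103 (stem cells) and 0.026 (differentiated cells). Other differences between the samples, with 2 libraries per group, stay open, as does correlation among the genes (camera adjusted p = 0.272 and 0.18 when estimated).

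Whole chromosomes held shifted shares of reads in single libraries of the knockout experiment. A change of the mark is argued against, since shifts in windows poor in 5hmC followed those in rich windows with a slope of 0.992 (SE 0.0148, 90 points). Among the controls, same-numbered hmeDIP and meDIP libraries had shifts correlated at 0.99 or more across 15 chromosomes, against −0.381 at most for other numbers, which is consistent with a different copy number of chromosomes in each sample. For knockout replicates 2 and 3 the crossed pairs correlated at 0.996 and 0.998 and the same-numbered pairs at −0.931 and −0.923, so a candidate explanation is that the numbers 2 and 3 were exchanged between the antibodies. No untreated DNA of these samples was used here, so copy number itself stays unmeasured.

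Changes of 5hmC and RNA ranked together across genes on differentiation. No chromosome was shifted by more than 0.0276 (log2) in any of the 8 hmeDIP libraries, which argues against chromosome copy number. With gene length, RNA level and 5hmC level held constant, the partial rho was 0.203 and 0.226, which argues against those properties as the whole source. A shared regulation of both and a changed mixture of cell types after 3 days stay open and were not tested.

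The 6 libraries of each antibody in the knockout experiment can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For 5hmC the real split gave 0 windows (highest other 1), 0 gene bodies (highest other 85) and 1 gene list (highest other 1). For 5mC it gave 1 window (highest other 101), 0 gene bodies (highest other 5) and 0 gene lists (highest other 3). A real count of 0 is matched by any split, so those counts test nothing. The split with 85 gene bodies set control 1, control 2 and knockout 3 against the rest and gave 0 after chromosomes were centred, and the split with 101 windows set control 1, control 2 and knockout 2 against the rest. The latter gave 5 gene bodies for 5mC and 25 after chromosomes were centred. By chromosome shifts, hmeDIP knockout 3 matched meDIP knockout 2 (correlation 0.998). Both splits may therefore set the same samples apart, each seen with another antibody. Counts of this size in other splits point to a structure of the samples. For the 85 gene bodies, the loss of all calls after centring argues that they followed the chromosome shifts. The source of the 5mC counts stays open.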
